A study of Arabidopsis thaliana with 18 samples.

How the data were processed

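Gene expression was measured in 18 whole-seedling samples of Arabidopsis thaliana, each on 1 Affymetrix array. Per the labels' protocols, total RNA was extracted with Trizol and 1 µg per sample was turned into biotin-labelled cRNA. The labels give 6 groups, from 2 genotypes (Col-0 and arp6-10) at 3 points (12 °C, and 2 h and 24 h after a shift to 27 °C), with 2 arrays in each Col-0 group and 4 in each arp6-10 group. The labels do not state whether arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

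The deposited table holds linear signal intensities per probe set, made with GCOS per the submitters' processing notes; its version and algorithm are not given in the sources used here. Values ran from 0 to 37829.8. The mean of the deposited intensities after removing 2% at each end lay between 249.9 and 251.28 on the 18 arrays, so the arrays share a common scale of this kind. The table holds 22810 probe sets, of which 64 are Affymetrix controls that were used only to describe the arrays. No detection calls were used here. The scale of fold changes below is log2(value + 16), which understates the change of dim genes and cannot go under 4. Where a group mean is under 5 the gene is not shown to be above background there, and its fold is a rough value. This holds for ROF2, Hop3 and HSP17.6C-CI in Col-0 at 12 °C, SWC2 in Col-0 at 12 °C and 2 h, AT2G01100, AT2G20550, POLD3 and AT5G51840 in Col-0 at 12 °C, CHR23 in Col-0 at 2 h, NDB4 and ICL in Col-0 at 24 h, and AT3G33530 and AT4G15690 in arp6-10 at 12 °C. Without the 2 doubted arrays it also holds for ROF2 and HSP17.6C-CI in arp6-10 at 12 °C.

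Array medians on that scale spanned 0.45 log2 units, from 6.27 to 6.72, more than the 0.3 allowed by the rule fixed before the data were examined, so quantile normalization between arrays (limma 3.58.1, R 4.3.3) was the main setting. The values as deposited are an alternative. Probe sets under the 30th percentile of the mean over all arrays were left out, and 15922 were tested. Each of 9 comparisons was a contrast in 1 model of the 6 group means (limma lmFit and eBayes with a trend, 12 residual degrees of freedom, two-sided). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison.

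Names came from the platform annotation given for the probe sets, with symbols updated through RefSeq's TAIR10.1 gene table. It pairs 13513 probe sets with 1 gene and 503 with several, and 8730 are not listed in it. Of the 13513, 13436 matched a RefSeq gene and 8745 were tested. Only probe sets paired with 1 gene are named. For 68 tested genes with several probe sets the one with the highest mean was used. No build is named by the sources, so no coordinates are printed.

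The genes named in each comparison follow a rule fixed before the data were examined: ARP6 and HSP70, the members of 17 fixed gene lists, and the 10 largest increases and 10 largest decreases among called genes whose 2 groups of arrays do not overlap (called alone for the differences of responses). ARP6 and HSP70 had no named probe set and are not analysed here. The same rule was applied to the fit without 2 doubted arrays, described with the results. Of 332 list members, 48 had a probe set paired with them alone and 45 of these were tested. The lists with at least 3 tested members covered heat shock (8), endoplasmic reticulum protein folding (3), cold response (5), warm growth and auxin response (3), photosynthesis (5), flavonoid and anthocyanin synthesis (4), ribosome biogenesis (6) and root markers (4). They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over these 8 lists per comparison, with an estimated correlation as an alternative. limma's fry asks whether the members move together in 1 direction, without comparing them with other genes. Its test of change in either direction is not given here. In Col-0, fry passed heat shock at 2 h (adjusted p = 5.02e-08). At 24 h it passed heat shock, endoplasmic reticulum folding, photosynthesis and cold response in Col-0 (0.00212, 0.033, 0.033 and 0.0497). It passed heat shock, endoplasmic reticulum folding and ribosome biogenesis in arp6-10 at 2 h (9.57e-10, 0.0029 and 0.00823) and between genotypes at 12 °C (0.00172, 0.00324 and 0.0101) and 2 h (0.000226, 0.00323 and 0.0167), and no list elsewhere with all arrays. The lists with 1 or 2 tested members (circadian clock, SWR1 complex, salicylic acid defence, jasmonate response, cell cycle) are given by member. Median, mean and camera direction differ in sign for root markers (Col-0 at 24 h, genotypes at 12 °C, difference at 24 h), cold response (arp6-10 at 2 h), endoplasmic reticulum folding (genotypes at 24 h) and ribosome biogenesis (both differences of responses), and none of these passed. Phosphate starvation, seed storage, floral organ and flowering time genes had no tested member.

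Simulated log2 values with 200 changed genes among 15922 were put through the same model, without the steps of normalization and filtering. Their noise was normal and independent between arrays, so the shares below hold only under these conditions. Of 2-fold changes, 34% were recovered in the comparison of Col-0 after 2 h, 69% in that of arp6-10 after 2 h, 47% between the genotypes at 12 °C and 19% in the difference of the 2 h responses. Of 4-fold changes, 91%, 98%, 96% and 80% were recovered in these comparisons. Unchanged genes were called 6, 17, 4 and 4 times. Alternatives fixed in advance were no filter or a filter at the 50th percentile, pseudocounts of 1 and 64, the values as deposited, eBayes without the trend, an added 2-fold threshold, a fit of the compared groups alone, the replicate number as a block, arp6-10 arrays 1 and 2 or 3 and 4 alone, and each array left out. Leaving out the 2 doubted arrays, and adding the GAPDH 3' to 5' ratio as a covariate, were chosen after seeing the data, as was a split of the 2 Col-0 12 °C arrays, 1 in each difference, in a model with each as its own group (11 residual degrees of freedom). Replicate numbers were not used as pairs: of 36 pairs of same-numbered arrays from different groups, 9 had residuals correlated over 0.1 (range -0.402 to 0.56). Within groups, arp6-10 2 h arrays 1 and 2 were nearest to each other (Spearman 0.982), as were 3 and 4 (0.976). The same held for arp6-10 24 h arrays 3 and 4 (0.977). If such arrays share a culture, they are not independent samples and the p-values are too small. The covariance of shared-control comparisons was simulated 50 times with fixed seeds.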

Results

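Seedlings of the Arabidopsis accession Col-0 and of the mutant arp6-10 were compared before and after a step from cool to warm conditions. ARP6 is an actin-related subunit of the SWR1 complex, which places the histone variant H2A.Z into nucleosomes, and the series title asks about the part of such nucleosomes in the response to temperature. Seeds were kept at 4 °C for 48 h and moved to 20 °C, and 5-day-old seedlings then spent 3 days at 12 °C in continuous light. Whole seedlings were collected at 12 °C and 2 h and 24 h after the shift to 27 °C. The labels give no group kept at 12 °C for those 2 h or 24 h. A change after the shift can therefore come from warmth or from the time elapsed, and these cannot be told apart. The ARP6 transcript itself has no named probe set and is not analysed here, so the mutation was not checked on it. Each Col-0 group has 2 arrays and each arp6-10 group 4, and this number of arrays limits the precision.

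Anthocyanin and cold-regulated genes showed that 2 arp6-10 arrays stand apart from their groups. The mean of the flavonoid list was 7.03 on the array labelled arp6-10 12 °C replicate 3 and 11.05 on the array labelled arp6-10 24 h replicate 2, on the log2 scale. Along the axis from the other arp6-10 12 °C arrays (0) to the other arp6-10 24 h arrays (1), over all tested probe sets, they lay at 0.96 and -0.04. The remaining arp6-10 12 °C arrays lay between 0.08 and 0.14 and the remaining 24 h arrays between 0.88 and 0.93. The groups below keep the labels as given, and the calls of each comparison are followed by their number from the 16 arrays without these 2. Since the 2 were set aside for these values, the results of the 16 arrays depend on that choice, those of Col-0 through the shared spread. The ratio of 3' to 5' signal of GAPDH, a measure of RNA integrity, ranged from 1.47 to 6.78. It was 5.51 on the first of these 2 arrays, the highest of its labelled group (others 1.47 to 4.28), and 1.51 on the second, the lowest of its group (others 1.94 to 6.48). Hybridization control signals were higher on the Col-0 arrays (2170 ± 348, SD, n = 6) than on the arp6-10 arrays (1637 ± 252, SD, n = 12).

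**Figure D1:**
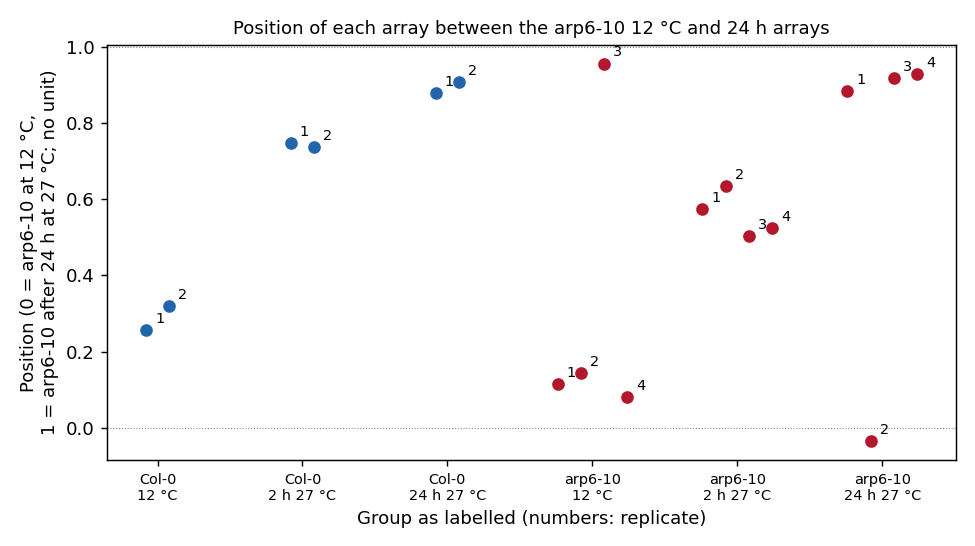
Position of each array along the axis from the arp6-10 12 °C arrays (0) to the arp6-10 24 h arrays (1), over all tested probe sets, by labelled group with replicate numbers. The 2 arrays at 0.96 and -0.04 were left out of the axis, and each other arp6-10 array was left out of its own axis.

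The first comparison asks what 2 h of warmth changed in wild-type seedlings. Heat shock genes were among the largest increases. The co-chaperone ROF2 (AT5G48570) increased 24.1-fold (log2 change 4.59 ± 0.73 SE), and the small heat shock proteins HSP17.6B-CI (AT2G29500) and HSP23.5 (AT5G51440) increased 10.8-fold (log2 change 3.43 ± 0.32 SE) and 10.4-fold (log2 change 3.38 ± 0.41 SE). HSP17.6B-CI stood at 9.91 ± 0.26 (SD, n = 2) against 6.48 ± 0.16 (SD, n = 2). Of the 8 heat shock list members tested, 6 rose and none fell, and 7 rose when adjusted over the list alone (camera adjusted p = 3.51e-08, and adjusted p = 0.000454 with an estimated correlation). HSP17.6C-CI (AT1G53540) rose 5.05-fold and HSA32 3.75-fold. Outside the list, AT5G12110 rose 18.6-fold, Hop3, a co-chaperone of HSP70 and HSP90, 7.54-fold, and the expansin-like gene EXLA1 6.95-fold. The log2 change of AT5G12110 was 4.22, and 5.17 or 3.25 without Col-0 12 °C replicate 1 or 2. AT5G62210 fell 6.38-fold, AT1G06000 5.67-fold and BCAT4, an aminotransferase of glucosinolate synthesis, 4.53-fold. ATERDJ3B, a chaperone of the endoplasmic reticulum, rose 3.31-fold as 1 of 3 members of its list (adjusted p = 0.322).

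Anthocyanin genes had large negative values after 2 h in Col-0. DFR, the dihydroflavonol reductase, had a log2 change of -3.59, the glycosyltransferases AT4G14090 and UF3GT -3.24 and -3.24, and UGT78D2 -1.74. None of the 4 passed the threshold over all probe sets, and all 4 fell when adjusted over the list alone (camera adjusted p = 0.0177, and adjusted p = 0.468 with an estimated correlation). All 4 fell without the 2 doubted arrays, DFR 12.2-fold (adjusted p = 4e-09, and adjusted p = 0.00159 with an estimated correlation). Those arrays were set aside for their flavonoid means and enter here through the shared spread, so these calls depend on that choice. Of 6 ribosome biogenesis genes, AT3G15460 (BRX1-1) and AT5G15550 (WDR12) fell 2.43-fold and 2.08-fold (adjusted p = 0.0355, and adjusted p = 0.468 with an estimated correlation). The cold, photosynthesis, root and warm growth lists did not pass (adjusted p = 0.788, 0.159, 0.656 and 0.799). In all, 695 probe sets rose and 563 fell in Col-0 after 2 h, and 1778 and 1599 without the 2 doubted arrays, which enter through the shared spread. The total of 1258 became 218 without Col-0 12 °C replicate 1, 356 and 554 without Col-0 2 h replicate 1 or 2, and 2013 without arp6-10 24 h replicate 2, and 2596 in a fit of the compared groups alone. Of 14 called changes of named genes in Col-0 at 2 h, 8 were not called with some 1 array left out, those of HSP17.6C-CI, HSA32, Hop3, EXLA1, AT5G62210, AT1G06000, BRX1-1 and WDR12.

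After 24 h of warmth, Col-0 seedlings had less of several cold-regulated transcripts. COR15A and COR15B, which encode cold-induced chloroplast proteins, fell 20-fold (log2 change -4.32 ± 1.15 SE) and 11-fold (log2 change -3.46 ± 0.89 SE), and STZ, a zinc finger repressor, fell 3.14-fold. COR15A stood at 6.54 ± 0.20 (SD, n = 2) against 10.86 ± 0.40 (SD, n = 2). Of the 5 cold genes tested 3 fell, and 4 fell when adjusted over the list alone (camera adjusted p = 0.0523). That value was 0.000225 without the 2 doubted arrays, and adjusted p = 0.0499 with an estimated correlation. GSTU25, a glutathione transferase, fell 14.5-fold, AT4G12490 8.75-fold and AT5G03350 8.08-fold. AT5G12110 remained 11.4-fold higher than at 12 °C and ROF2 (AT5G48570) 8.62-fold, while AT3G24100 was 10.2-fold higher and PGRL1B, of photosynthetic electron flow, 7.07-fold higher. The log2 change of AT5G12110 was 3.51, and 4.47 or 2.55 without Col-0 12 °C replicate 1 or 2 (not called in the last case, adjusted p = 0.0544). The photosynthesis genes PRK and PSAE-1 rose 2.2-fold and 1.68-fold, 2 of 5 members, and all 5 when adjusted over the list alone (adjusted p = 0.0373, and adjusted p = 0.53 with an estimated correlation).

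Other listed genes of Col-0 at 24 h went separate ways. Of the heat shock members 3 rose, among them HSP23.5 (AT5G51440) by 2.59-fold and Hsp70-2 by 1.59-fold (adjusted p = 0.0523). The ribosome biogenesis genes AT3G05060 (NOP58B) and AT2G40430 (SMO4) rose 2.37-fold and 1.87-fold, and the list did not pass (adjusted p = 0.912). ATERDJ3B rose 4.2-fold, SWC2, a subunit of the SWR1 complex, 2.61-fold, and NAI2, of root endoplasmic reticulum bodies, 2.63-fold, while the defensin PDF1.2 fell 2.92-fold. The clock gene GI had a log2 change of -0.50 and the salicylic acid genes WRKY53 and GRX480 of 0.31 and -0.36, none past the threshold. The endoplasmic reticulum, flavonoid, warm growth and root lists did not pass (adjusted p = 0.472, 0.146, 0.806 and 0.743). In all, 1645 probe sets rose and 1130 fell in Col-0 after 24 h, and 2682 and 2288 without the 2 doubted arrays. With the values as deposited the split was 2484 higher and 985 lower, and the median of all probe sets shifted by 0.14 log2. The total of 2775 became 1065 or 1551 without Col-0 12 °C replicate 1 or 2 and 464 without Col-0 24 h replicate 1. With each array left out in turn, only the calls of ATERDJ3B and AT5G03350 at 24 h held throughout, and the other 18 named ended at least once.

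Heat shock genes were also the leading group in arp6-10 after 2 h of warmth. ROF2 (AT5G48570) rose 26.5-fold (log2 change 4.73 ± 0.52 SE), HSP17.6B-CI (AT2G29500) 24.9-fold (log2 change 4.64 ± 0.23 SE), and HSP23.5 (AT5G51440) 15.4-fold (log2 change 3.94 ± 0.29 SE), and HSP17.6C-CI (AT1G53540) rose by 4.15 ± 0.34 (SE) log2 units. Without arp6-10 12 °C replicate 3 the log2 change of ROF2 was 5.37 and that of AT2G23910, named below, -3.22 in place of -2.62. HSP17.6B-CI stood at 11.47 ± 0.29 (SD, n = 4) against 6.83 ± 0.31 (SD, n = 4). Of the 8 heat shock members 5 rose and none fell (camera adjusted p = 8.28e-11, and adjusted p = 0.000111 with an estimated correlation). Hop3 rose 9.57-fold, AT5G12110 7.1-fold and AT3G10020 5.32-fold. AT2G23910 fell 6.14-fold, CHIL, a chalcone isomerase-like protein of flavonoid synthesis, 4-fold, and AT1G06000 3.98-fold. UGT78D2 fell 3.17-fold as 1 of 4 flavonoid members, and all 4 fell when adjusted over the list alone (adjusted p = 0.00526, and adjusted p = 0.252 with an estimated correlation). Of 6 ribosome biogenesis genes 3 fell, AT3G05060 (NOP58B) by 1.96-fold (adjusted p = 5.24e-05, and adjusted p = 0.127 with an estimated correlation). ATERDJ3B rose 2.2-fold (list adjusted p = 0.015, and adjusted p = 0.0773 with an estimated correlation), and the replication gene PRL (MCM7) fell 1.74-fold while AUR1 had a log2 change of -0.01. The cold, photosynthesis, root and warm growth lists did not pass (adjusted p = 0.888, 0.495, 0.888 and 0.193).

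The arrays labelled arp6-10 2 h and arp6-10 12 °C differed at 589 probe sets, 296 higher and 293 lower after the shift, including the heat shock genes above. With the values as deposited the split was 265 higher and 446 lower. Without the 2 doubted arrays 1334 rose and 1375 fell, and DFR, UF3GT and AT4G14090 then fell 11-fold, 9.01-fold and 7.46-fold, while the growth gene EXPA8, an expansin, rose 3.91-fold. Calls of Col-0 and arp6-10 met at 91 probe sets that rose in both and 91 that fell in both. The compared groups share no array here, but both comparisons use the same estimate of spread per probe set, so the lists are not independent. Independent lists of these sizes give 12.9 and 10.4. On the 16 arrays these were 580 and 651, against 149 and 138. The count of 589 became 355, 196, 1422 and 249 without arp6-10 12 °C replicate 1, 2, 3 or 4. It became 364, 228, 269 and 210 without arp6-10 2 h replicate 1, 2, 3 or 4, and 1124 without arp6-10 24 h replicate 2. Among the 14 named calls, those of AT1G06000, AT2G23910, NOP58B, CHIL, PRL and UGT78D2 ended with some 1 array left out.

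Between the arrays labelled arp6-10 24 h and arp6-10 12 °C, no gene passed the threshold. DFR had a log2 change of -2.18, COR15A of -1.75 and EXPA8 of 1.29, each with 1 array of either group on the other group's side. COR15A stood at 8.99 ± 1.71 (SD, n = 4) against 10.74 ± 2.07 (SD, n = 4). limma called 0 probe sets, with 1691 at an unadjusted p under 0.05. The flavonoid, ribosome biogenesis and photosynthesis lists passed camera (adjusted p = 0.0107, 0.00544 and 0.038). Their values were adjusted p = 0.297, 0.296 and 0.396 with an estimated correlation. The heat shock, cold, endoplasmic reticulum, warm growth and root lists did not pass (adjusted p = 0.111, 0.111, 0.94, 0.0505 and 0.228).

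Without the 2 doubted arrays, anthocyanin genes had lower values in arp6-10 after 24 h. These 2 arrays were set aside for their place on this same axis and their flavonoid means, so the folds, counts and p-values of this paragraph depend on that choice and are no independent test of it. DFR fell 24.7-fold (log2 change -4.62 ± 0.22 SE), AT4G14090 16-fold and UF3GT 14.9-fold, and all 4 flavonoid members fell (camera adjusted p = 7.18e-09, and adjusted p = 0.00356 with an estimated correlation). COR15A and COR15B fell 12.6-fold and 6.79-fold with the dehydrin LTI30 at 4.38-fold, 3 of 5 cold members (adjusted p = 0.000228, and adjusted p = 0.0539 with an estimated correlation). EXPA8 rose 7.17-fold and WES1, which conjugates auxin to amino acids, 1.95-fold, while GH3.3, the third warm growth member, had a log2 change of 0.02 (list adjusted p = 0.0105, and adjusted p = 0.0555 with an estimated correlation). All 3 photosynthesis members that passed rose, LHCB4.2 by 3.84-fold, and 5 of 6 ribosome biogenesis members fell. In all 2228 probe sets rose and 2366 fell among these 16 arrays. Leaving out the array labelled 12 °C replicate 3 alone gave 430 calls, and the array labelled 24 h replicate 2 alone 1518.

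**Figure D2:**
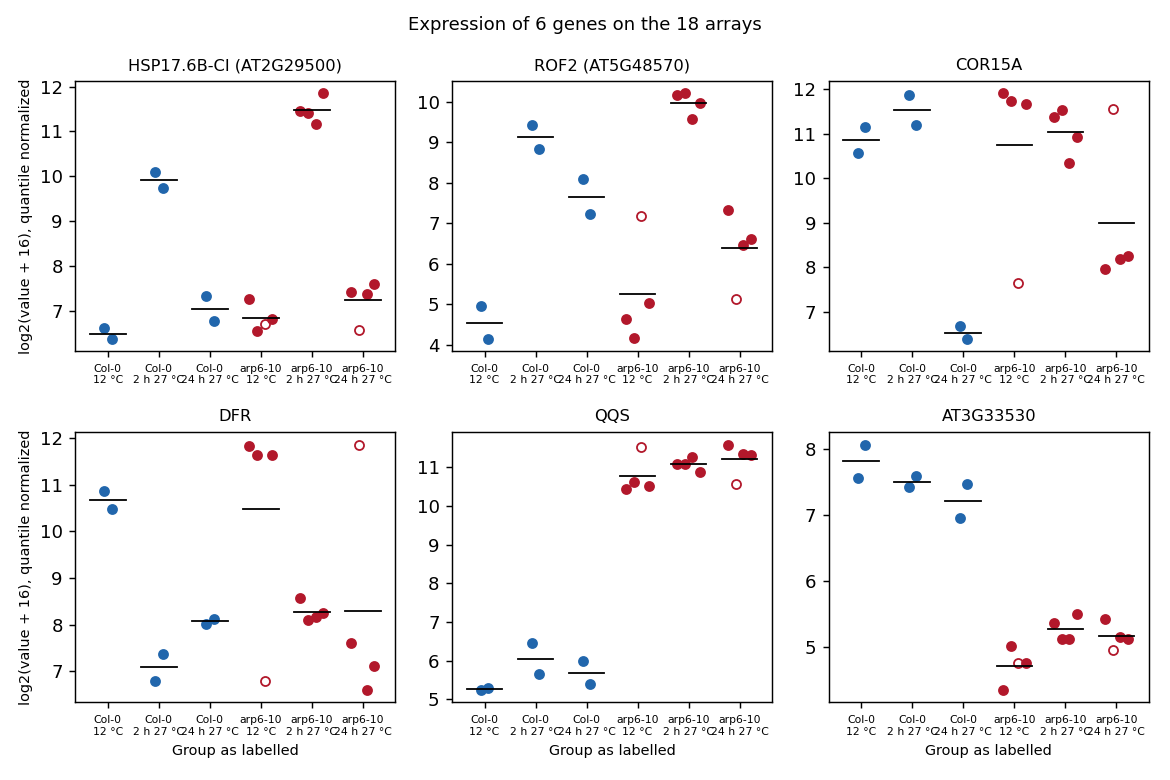
Expression of 6 genes as log2(value + 16) after quantile normalization, by labelled group; each circle is 1 array, bars are group means, and open circles are the 2 doubted arrays. QQS is higher on every arp6-10 array than on every Col-0 array, and AT3G33530 is lower.

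Before the shift, at 12 °C, arp6-10 differed from Col-0 in a large share of the transcripts measured. QQS, an orphan gene that affects starch content, was 45.4-fold (log2 change 5.50 ± 0.32 SE) higher in arp6-10, at 10.77 ± 0.51 (SD, n = 4) against 5.26 ± 0.04 (SD, n = 2). AT1G65370 and AT1G54410 were 12.2-fold and 12.2-fold higher, and AT2G01100 was higher at 7.88 ± 0.57 (SD, n = 4) against 4.25 ± 0.15 (SD, n = 2), again from close to the lowest value. AT3G33530, the locus numbered next to ARP6, was 8.62-fold (log2 change -3.11 ± 0.23 SE) lower, and AT5G56100, AT5G18600 and AT4G15690 were 5.63-fold, 5.14-fold and 5.07-fold lower. SWC2, another subunit of the complex that holds ARP6, was higher, at 6.39 ± 0.20 (SD, n = 4) against 4.38 ± 0.12 (SD, n = 2), the latter close to the lowest value the scale allows. Of 6 ribosome biogenesis genes, AT3G05060 (NOP58B) and AT2G40430 (SMO4) were 5.57-fold and 4.85-fold higher. Of 8 heat shock members, Hsp70-2 and HSP23.5 (AT5G51440) were higher by 2.92-fold and 2.42-fold, while HSP17.6B-CI (AT2G29500), with a log2 difference of 0.35, and ROF2 (AT5G48570), with 0.71, did not pass. The chaperones CRT1b and ATERDJ3B were 1.74-fold and 3.28-fold higher, COR47 1.93-fold higher and STZ 2.27-fold lower. PDF1.2 was 2.61-fold lower and WES1 1.74-fold lower. None of the 8 lists passed camera, with adjusted p from 0.217 for heat shock and 0.217 for ribosome biogenesis to 0.998 for cold response.

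In all, 2806 probe sets were higher and 2338 lower in arp6-10 at 12 °C, 32.31% of those tested, and 3291 and 2915 without the 2 doubted arrays. The genotypes also differ in hybridization control signal, as given above, and in array median before normalization. At 12 °C these medians were 6.39 and 6.27 in Col-0 and 6.52 to 6.71 in arp6-10. They cannot be compared within a batch because the labels give none. With the values as deposited, 3693 were higher and 1808 lower. The total of 5144 became 2698 and 3221 without Col-0 12 °C replicate 1 or 2, and 3230 in a fit of these 2 groups alone. COR15A, with a log2 difference of -0.12 as labelled, was 1.89-fold higher without the 2 doubted arrays, and EXPA8 was 3.85-fold lower. The calls at 12 °C of HSP23.5, COR47, CRT1b, PDF1.2, STZ and WES1 ended with some 1 array left out, and the other 13 named held.

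After 2 h at 27 °C, 4 of 8 heat shock members were higher in arp6-10 than in Col-0 and none was lower. HSP17.6C-CI (AT1G53540) was 4.59-fold higher, HSP23.5 (AT5G51440) 3.57-fold (log2 change 1.83 ± 0.35 SE), HSP17.6B-CI (AT2G29500) 2.94-fold and Hsp70-2 1.61-fold (camera adjusted p = 0.00978, and adjusted p = 0.0699 with an estimated correlation). HSP23.5 and Hsp70-2 were already higher at 12 °C. QQS was 32.7-fold higher, AT1G65370 8.76-fold, and CHR23, a chromatin remodelling ATPase, 4.91-fold. The thionin THI2.2 was 7.04-fold lower, AT1G66100 7.01-fold, MAP1B, a methionine aminopeptidase, 4.77-fold and AT3G33530 4.7-fold lower. The ribosome biogenesis genes AT3G05060 (NOP58B) and AT2G40430 (SMO4) were 2.99-fold and 2.91-fold higher (adjusted p = 0.00978, and adjusted p = 0.345 with an estimated correlation). SWC2 was 2.29-fold higher, as were CRT1b and ATERDJ3B by 2.21-fold and 2.17-fold (list adjusted p = 0.0584). The cold, flavonoid, photosynthesis, root and warm growth lists did not pass (adjusted p = 0.662, 0.662, 0.845, 0.244 and 0.937).

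At that time 823 probe sets were higher and 650 lower in arp6-10, and 1675 and 1409 without the 2 doubted arrays, which belong to other groups and enter through the shared spread. The values as deposited gave 1272 higher and 573 lower, and the offset in hybridization control signal between the genotypes applies here too. Array medians before normalization also differed, at 6.34 and 6.41 in Col-0 and 6.49 to 6.53 in arp6-10. The total of 1473 became 834 or 177 without Col-0 2 h replicate 1 or 2, and 843, 977 and 920 without arp6-10 2 h replicate 1, 2 or 3. It was 3112 in a fit of the compared groups alone. Of 16 named calls at 2 h, those of QQS, AT1G65370, CHR23, MAP1B, AT3G33530, SMO4 and HSP17.6C-CI held with any 1 array left out, and those of the other 9 ended at least once, among them HSP23.5, HSP17.6B-CI and Hsp70-2.

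After 24 h at 27 °C few genes were called between the genotypes, which does not show that the others were alike. limma gave 2333 probe sets an unadjusted p under 0.05. QQS was 46.1-fold (log2 change 5.53 ± 0.32 SE) higher in arp6-10 and AT1G65370 6.89-fold higher. NDB4, a mitochondrial NAD(P)H dehydrogenase, was 6.1-fold higher and ICL, the isocitrate lyase of the glyoxylate cycle, 5.82-fold. AT1G47400 was 9.38-fold (log2 change -3.23 ± 0.45 SE) lower, AT5G09240 4.21-fold, AT3G33530 4.16-fold, MAP1B 3.88-fold and the defensin-like PDF2.5 2.77-fold lower. COR15A and COR15B had log2 differences of 2.45 and 2.46 that did not pass as labelled. They were, without the 2 doubted arrays, 3.04-fold and 3.28-fold higher in arp6-10. The cold list passed (camera adjusted p = 0.0221, and adjusted p = 0.732 with an estimated correlation), with 0 of 5 members called. The ribosome biogenesis list also passed, with AT2G40430 (SMO4) 1.96-fold higher (adjusted p = 0.0301, and adjusted p = 0.732 with an estimated correlation). On the doubted array, 24 h replicate 2, the ribosome biogenesis mean was 9.93. The other arp6-10 24 h arrays gave 8.91 to 9.16 and Col-0 8.997 and 8.71. The cold mean on that array was 10.35, against 8.14 to 8.73 on the others and 7.45 and 7.49 in Col-0. The labelled excess of both lists therefore comes in part from that array. Hsp70-2 was 1.67-fold higher, the 1 heat shock member called (adjusted p = 0.534). Flavonoid genes had a list adjusted p of 0.84 and DFR a log2 difference of 0.23 as labelled, and without the 2 doubted arrays DFR and UF3GT were 1.95-fold and 2.04-fold lower in arp6-10 (list adjusted p = 0.0022, and adjusted p = 0.0643 with an estimated correlation). The photosynthesis, endoplasmic reticulum, root and warm growth lists did not pass (adjusted p = 0.186, 0.84, 0.84 and 0.96).

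The 24 h comparison called 76 probe sets higher and 72 lower, and 261 and 217 without the 2 doubted arrays. Hybridization control signals were on average higher in Col-0 here as well (2044 against 1663), but the arrays overlapped, 1948 and 2140 against 1287 to 2177. Array medians before normalization overlapped too, 6.65 and 6.55 in Col-0 and 6.59 to 6.72 in arp6-10. The total of 148 became 33 or 28 without Col-0 24 h replicate 1 or 2, 275 without arp6-10 12 °C replicate 3, and 86 or 91 without arp6-10 24 h replicate 3 or 4. It was 17 in a fit of the compared groups alone. Genes such as QQS, AT1G65370 and NDB4 were called in the same direction at all 3 times, with 34 probe sets higher and 44 lower in arp6-10 throughout, and 105 and 95 without the 2 doubted arrays. Calls of QQS, AT1G65370, ICL, AT3G33530 and AT5G09240 held with any 1 array left out, and those of AT1G47400, NDB4, MAP1B, PDF2.5, SMO4 and Hsp70-2 ended at least once. The call of SMO4 ended in 17 of 18 such fits, that of Hsp70-2 in 7 and the others in 1 or 2.

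**Figure D3:**
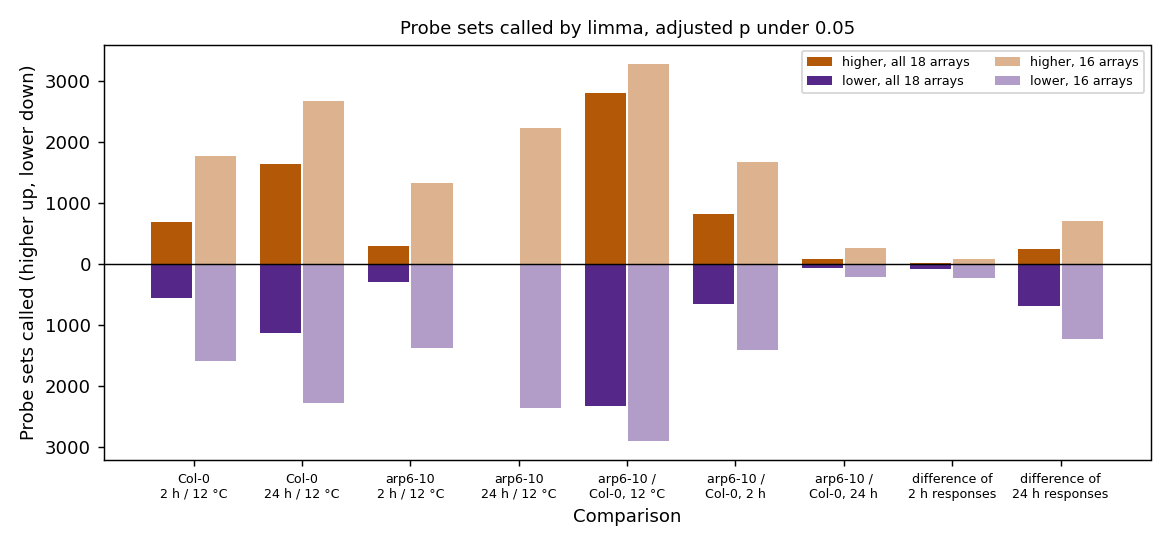
Number of probe sets called by limma in each of the 9 comparisons, higher upwards and lower downwards, with all 18 arrays (dark) and without the 2 doubted arrays (light). The arp6-10 comparison of 24 h with 12 °C goes from 0 calls to 4594.

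The difference between the 2 responses at 2 h was tested directly. The response of AT1G54410, a dehydrin, was more negative in arp6-10 by 6.47-fold (log2 change -2.69 ± 0.40 SE), that of AT2G20550 by 4.71-fold and that of POLD3, a DNA polymerase subunit, by 4.2-fold. The response of AT1G29090 was more positive in arp6-10 by 4.16-fold (log2 change 2.06 ± 0.44 SE), that of AT4G32440 by 3.5-fold and that of CSLC12, a cellulose synthase-like gene, by 2.5-fold. A single Col-0 group can carry such a difference. AT1G29090 stood at 8.00 and 7.87 in Col-0 at 12 °C, 5.55 and 5.34 at 2 h, and 4.99 to 6.01 in arp6-10 at both. CSLC12 stood apart in Col-0 at 2 h (4.97 and 5.71), with 6.12 to 6.64 on the other arrays compared. No heat shock member passed. HSP17.6C-CI (AT1G53540) had a difference of 1.81 log2 units and HSP17.6B-CI (AT2G29500) of 1.21. HSP17.6C-CI passed without the 2 doubted arrays, with a difference of 2.11 log2 units (adjusted p = 0.0186), a rough value since both 12 °C means are then near background. None of the 8 lists passed (adjusted p from 0.793 to 0.824). In all 94 probe sets differed, 13 more positive and 81 more negative in arp6-10, and 80 and 235 without the 2 doubted arrays. With the values as deposited 6 were more positive and 91 more negative. The count of 94 became 24 or 210 without Col-0 12 °C replicate 1 or 2, and 9 or 62 without Col-0 2 h replicate 1 or 2. For arp6-10 it became 46, 23 and 56 without 12 °C replicate 1, 2 or 3, 53, 21 and 21 without 2 h replicate 2, 3 or 4, and 154 or 46 without 24 h replicate 2 or 4. It was 0 or 1 with arp6-10 arrays 1 and 2 or 3 and 4 alone, 28 in a fit of the compared groups, 59 or 28 with replicate blocks, 47 with the 50th percentile filter, and 182 or 23 with pseudocounts of 1 or 64. Of the 6 genes named as called, only POLD3 held with any 1 array left out.

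The same difference at 24 h involved more genes. The response of AT1G54410 was more negative in arp6-10 by 7.77-fold (log2 change -2.96 ± 0.40 SE), that of AT1G47400 by 7-fold, AT5G51840 by 6.68-fold and AT2G01100 by 6.43-fold. That of AT3G23550 was more positive by 6.75-fold (log2 change 2.75 ± 0.58 SE), AT1G29090 5.6-fold, AT5G03350 5-fold and the defensin PDF1.2 4.7-fold. Here too 1 Col-0 group can carry the difference. AT5G51840 stood at 4.59 and 4.24 in Col-0 at 12 °C, 7.22 and 6.95 at 24 h, and 6.59 to 7.49 in arp6-10 at both. AT1G47400 stood apart in Col-0 at 24 h (10.59 and 11.09), with at most 8.80 on the other arrays compared. Among listed genes, SWC2, AT3G05060 (NOP58B), AT2G40430 (SMO4), ATERDJ3B and Hsp70-2 were more negative in arp6-10, by 2.9-fold, 3.35-fold, 2.47-fold, 3.48-fold and 1.75-fold. STZ was 3.42-fold more positive. None of the 8 lists passed (adjusted p from 0.27 for heat shock, cold and photosynthesis to 0.866 for root markers). The flavonoid list passed without the 2 doubted arrays, with DFR 4-fold more negative in arp6-10 where it had a log2 difference of 0.42 as labelled (list adjusted p = 0.000419, and adjusted p = 0.0556 with an estimated correlation), and EXPA8 was 3.21-fold more positive. In all 929 probe sets differed, 238 more positive and 691 more negative in arp6-10, and 1933 without the 2 doubted arrays, 708 and 1225. With the values as deposited 208 were more positive and 1054 more negative. The total became 455 without Col-0 12 °C replicate 1, 96 without Col-0 24 h replicate 1 and 478 in a fit of the compared groups alone. Only AT1G54410 and AT5G51840 of 14 named calls held with any 1 array left out.

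The last comparison asks whether genes that differ in arp6-10 at 12 °C are those that change in Col-0 after the shift. SWC2, AT3G05060 (NOP58B), AT2G40430 (SMO4), ATERDJ3B, HSP23.5 (AT5G51440) and Hsp70-2 were higher in arp6-10 at 12 °C and rose in Col-0 after 24 h, while STZ and PDF1.2 were lower in arp6-10 and fell. Of these, only ATERDJ3B kept both calls with any 1 array left out. COR15A, which fell 20-fold in warm Col-0, had a log2 difference of -0.12 in arp6-10 at 12 °C as labelled and of 0.92 without the 2 doubted arrays. Of the probe sets higher in arp6-10 at 12 °C, 1293 also rose in Col-0 after 24 h, of those lower, 674 also fell, and 3 were called in opposite directions. Independent lists of these sizes would share 290 and 166. On the 16 arrays 1654 and 1014 were shared, against 554 and 419, and 239 were opposite. The covariance of the 2 differences over all tested probe sets was 0.372 (Pearson r 0.715 across probe sets, which are not independent replicates), beside 0.0588 (r 0.578) simulated for unchanged groups sharing the Col-0 12 °C arrays. For the 2 h response, 522 were higher and rose and 199 were lower and fell, against 122 and 82.7 for independent lists and 28 opposite, with a covariance of 0.217 (r 0.494) beside 0.0586 (r 0.578) simulated. On the 16 arrays these were 1008 and 470, against 368 and 293, with 292 opposite. Leaving out the 2 doubted arrays, the covariances at 24 h and 2 h were 0.309 and 0.172, beside 0.0379 simulated for each. With the 2 Col-0 12 °C arrays split, 1 in each difference and both ways round, no array was shared. The covariance was then 0.323 or 0.316 at 24 h and 0.183 or 0.146 at 2 h, and 0.262 or 0.251 and 0.14 or 0.1 without the doubted arrays. At 24 h 508 or 592 were higher and rose, against 93.4 or 115 for independent lists, and 124 or 138 were lower and fell, against 22.4 or 30.1. At 2 h 101 or 281 were higher and rose, against 19.8 or 68.4, and 14 or 32 were lower and fell, against 4.31 or 19.2, with 6 or 31 opposite. On the 16 arrays the lower overlap at 2 h was 127 or 155, against 81.4 or 145, with 111 or 309 opposite. A shift common to both Col-0 12 °C arrays would still enter both differences, and neither the split nor the simulation removes it. Both differences also use 1 estimate of spread per probe set, so the counts for independent lists are only a rough reference.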

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

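The tests of the 2 out-of-place arrays, the splits of the arp6-10 arrays at 24 h and 12 °C, the adjustment for the GAPDH ratio, and the measuring of the 12 °C difference on arrays not used for its calls were chosen after the result was seen. The difference of the responses between genotypes was called at 94 probe sets for 2 h and 929 for 24 h, as given in the comparisons above.

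The array labelled arp6-10 12 °C replicate 3 lay far from the other 3 of its group on the arp6-10 axis (0.956), on the axis of the Col-0 response (1.09), in the mean of the cold list (7.99) and in the mean of the flavonoid list (7.03). The array labelled arp6-10 24 h replicate 2 lay apart on the same axes (-0.036 and 0.538), and in the means of the endoplasmic reticulum (9.97), flavonoid (11.05) and warm growth lists (7.02). Among the named genes, 12 had 1 array apart in the arp6-10 12 °C group (replicate 3 in 11 of them), 18 in the 24 h group (replicate 2 in 17 of them) and 2 in the 2 h group. These are out of 73 genes in each group, and with Dixon's 95% critical value chance sets about 1 in 20 groups apart. That rate holds for 1 gene alone. The genes lie on the same arrays and can move together, and the naming rule was also applied without these 2 arrays. The counts are therefore no independent test of the 2 arrays.

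A candidate explanation for the 2 arrays is an exchange of labels, tubes or plants between the arp6-10 12 °C and 24 h groups. It stays open, since the positions of the arrays, 0.956 and -0.0357, are what raised the doubt and cannot also test it. A mixture of both RNAs would put both near the middle and is argued against by these positions. Low array quality is argued against by their correlation with other arrays: the lower of their best Spearman correlations was 0.9744, above the median of the other 16 arrays, 0.9709. Their GAPDH ratios, 5.51 and 1.51, are the highest and the lowest of their labelled groups. Wrong handling of the plants and wrong labels of the tubes were not told apart by any value here, and no sample was moved to another group.

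The labelled split of the 8 arp6-10 arrays at 12 °C and 24 h calls 0 probe sets, so each of the 35 splits calls at least as many whatever the cause, and this comparison decides nothing. The highest other, 5866, is the split already seen on the axis, and the remaining ones call 0 to 2. For arp6-10 after 2 h, 1 of 35 splits, the labelled one, gave 589 calls and the highest other gave 0. This argues against chance in how these arrays fell into groups but cannot exclude it, since only 35 splits exist. The splits also treat the 8 arrays as independent. At 2 h 1 of 35 splits gave 2709 calls without the 2 doubted arrays, with 678 as the highest other. For 24 h the labelled split gave 4594 and the highest other 0, and 10 splits are too few for a share under 0.05.

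arp6-10 differed from Col-0 at 5144 probe sets at 12 °C and at 148 after 24 h. A constant offset between the arrays of the genotypes as the whole cause would keep the ratio of the 24 h difference to the 12 °C difference near 1, also where probe sets were called on 1 Col-0 and 1 or 2 arp6-10 arrays at 12 °C and measured on the others. That ratio was 0.156 to 0.398 over 8 such choices of arrays, and 0.141 to 0.393 without the 2 doubted arrays, which argues against it, with ratios at 2 h of 0.464 to 0.621 and 0.484 to 0.681. With the GAPDH ratio as a covariate 5729 probe sets were called at 12 °C. That ratio is extreme within its labelled group on both doubted arrays, so the covariate can also take up spread that they cause. The count therefore cannot decide on RNA integrity, which stays open. At 12 °C the ratios overlapped, 1.99 to 3.06 in Col-0 and 1.47 to 5.51 in arp6-10. A single outlying Col-0 array is argued against by 2698 and 3221 calls with 1 or the other left out, although 1 array then stands for its group and is assumed to vary like the others. A genotype effect that depends on temperature or on the time elapsed stays open. So does a difference between the Col-0 12 °C plates and the others, since the labels name no plate or batch.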

How the results depend on the processing

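The count for Col-0 after 2 h was 805 with a 2-fold threshold and 2596 in a fit of the compared groups, and for 24 h 1670 with a 2-fold threshold. Leaving out 1 array, the first ran from 218 to 2013 and the second from 464 to 3750. The arp6-10 2 h count was 179 with a 2-fold threshold, 1133 with the GAPDH covariate, and 78 or 57 with arrays 1 and 2 or 3 and 4, and with 1 array left out it ran from 196 to 1422; the 24 h count ran from 0 to 1518. Between genotypes a 2-fold threshold gave 2179 at 12 °C, 663 after 2 h and 94 after 24 h, the GAPDH covariate 272 at 24 h, and arrays 1 and 2 or 3 and 4 gave 543 or 597 at 2 h and 58 or 89 at 24 h. A fit of the compared groups gave 3230, 3112 and 17 at the 3 times, and 1 array left out gave 2698 to 5757, 177 to 1990 and 28 to 275. The 2 h difference of responses gave 47 with the 50th percentile filter, 182 and 23 with pseudocounts 1 and 64, 28 in a fit of the compared groups, 59 or 28 with replicate blocks, and 0 or 1 with arrays 1 and 2 or 3 and 4; the 24 h difference gave 151 or 319 with those arrays and 478 in a fit of the compared groups. With 1 array left out these differences ran from 9 to 210 and from 96 to 1097. The 16 arrays without the doubted ones gave 3377, 4970, 2709, 4594, 6206, 3084, 478, 315 and 1933 in the order of the comparisons. Other settings kept each count within 1.5 times. Of 114 called changes of named genes, 70 were not called with some 1 array left out, and none changed direction.

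The covariance beyond the simulated one, 0.158 at 2 h and 0.313 at 24 h, became 0.126 and 0.244 without a filter, 0.277 and 0.518 with pseudocount 1, 0.0828 and 0.17 with 64, 0.132 and 0.262 with arrays 1 and 2, 0.194 and 0.374 with arrays 3 and 4, and 0.134 and 0.271 without the 2 doubted arrays. With the 2 Col-0 12 °C arrays split it was 0.183 or 0.146 and 0.323 or 0.316. With 1 array left out it ran from 0.108 to 0.195 and from 0.258 to 0.36. COR15A at 12 °C had, without the 2 doubted arrays, a log2 difference of 0.92 against -0.12, DFR at 24 h -0.96 against 0.23 and DFR in the 24 h difference of responses -2.002 against 0.42, and the flavonoid list turned to passing in those 2 comparisons (camera adjusted p = 0.0022 and 0.000419, and adjusted p = 0.0643 and 0.0556 with an estimated correlation).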

Other observations

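The gene families in this part, grouped by symbol, were chosen after seeing the data, and none of their camera results holds with an estimated correlation. Of 9 genes named VPS, for vacuolar protein sorting, 4 rose in Col-0 at 2 h and 4 at 24 h and none fell (camera adjusted p = 0.0105 and 0.0161 over 21 families, and adjusted p = 0.276 and 0.471 with an estimated correlation). VPS2.2 had log2 changes of 1.48 at 2 h and 2.56 at 24 h and VPS60.1 of 1.65 and 1.12. PRA1 genes, whose products act in vesicle traffic, were lower in arp6-10 at 12 °C in 8 of 10 cases (adjusted p = 0.0169, and adjusted p = 0.325 with an estimated correlation), among them PRA1.A1 by a log2 difference of -1.03 and PRA8 of -1.10. PRA1.H had 0.48 and PRA7 -0.38, neither past the threshold.

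Plastid-encoded genes, 69 of them tested, had a median log2 change of 0.23 between the arrays labelled arp6-10 24 h and 12 °C, with 0 called by limma (camera adjusted p = 2.61e-06, and adjusted p = 0.914 with an estimated correlation). Without the 2 doubted arrays, set aside for their place on this same axis, 27 rose and 1 fell, with a median of 0.51 (adjusted p = 0.000416, and adjusted p = 0.966 with an estimated correlation). This number depends on that choice and is no independent test. In Col-0 over the same time 2 rose and 3 fell, with a median of -0.16.

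A hypothesis set down before its test was that genes differing between the genotypes at all 3 times lie on a chromosome segment around ARP6, since AT3G33530 stands next to it. Leaving out AT3G33530, QQS and MAP1B, which had been seen, 0 of 41 such genes lay within 100 tested genes either side of ARP6, where 0.936 were expected (1-sided Fisher exact p = 1). Without the 2 doubted arrays 1 of 110 did, where 2.51 were expected. With so few expected, these values cannot tell whether such a segment exists, and it stays open.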
